A study of Mus musculus with 6 samples.

How the data were processed

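RNA was sequenced from mammosphere cultures of MMTV-Neu mice, a line in which the mouse mammary tumour virus promoter drives the rat Neu (ErbB2) oncogene in the mammary epithelium. There were 6 libraries in 2 groups of 3. The early lesion (EL) spheres came from mammary glands of FvB mice aged 14 to 18 weeks without a palpable tumour, and the primary tumour (PT) spheres from tumours of mice older than 20 weeks. Although the protocol speaks of mammary glands, a tissue label of the EL samples also names lung. Per the labels' protocols, the tissue was digested, the cells were kept for 7 days on non-adherent plates in mammosphere medium, polyadenylated RNA was extracted, and the libraries were read on an Illumina MiSeq. The labels give no cell sort or selection beyond growth as spheres, and nothing in them says whether the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

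Per the submitters' processing notes, the reads were processed with STAR, featureCounts and DESeq2, and the builds mm10 and hg19 were used. Versions, parameters and the strand setting are not given in the sources used here. The deposited files hold raw whole-number counts per RefSeq transcript, made by the authors and not normalised, with a gene symbol on each row. No row lacks a gene name. A complete file has 33068 transcript rows, and the counts of the 5 complete files sum to between 72808910 and 85126630 per library. These sums may exceed the number of reads, because a read appears to have been counted again for other transcripts of a gene that it overlaps. In EL replicate 2, the 2 highest transcripts lay within 5% of each other for 81.3% of 3619 genes with several transcripts and at least 100 counts.

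The table of EL replicate 1 breaks off inside a row after 27664 transcripts, so 5404 transcripts, which hold all transcripts of 4170 symbols, have no value there. The rows absent from it carry between 5.54% and 6.96% of the counts of the other 5 libraries. The comparison of the groups therefore used the rows present in all 6 libraries, with 1 transcript per symbol, the one with the highest mean count, which gave 19893 symbols. Genes that are missing from EL replicate 1 were tested apart in the 5 complete libraries, 2 EL against 3 PT. Both decisions were made after the tables had been seen. Genes that overlap, antisense partners and near-identical paralogs cannot be told apart in these counts. Reads of the rat transgene were not separated from those of mouse Erbb2. Gene positions are those of the mm10 build (GRCm38), from a RefSeq table that matched 98.7% of the transcripts.

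Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr and libraries were scaled by TMM factors. The quasi-likelihood test compared PT with EL, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are PT minus EL and carry standard errors (SE). Expression values are CPM, counts scaled to a common library size with the TMM-scaled totals of the chosen transcripts. They are given as mean ± SD with n = 3 per group. The TMM factors lay between 0.914 and 0.922 for EL and near 1.09 for PT. For a gene with 0 counts in 1 group, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% interval. Both cover counting error only.

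A set of 34 gene lists with 592 distinct symbols was fixed from textbook knowledge, together with the test, the alternatives and the rule for naming genes, before the data were examined. The lists cover epithelial and mesenchymal programs, mammary cell types, signalling, the cell cycle, metabolism and stress, and markers of other cell types that digested tissue can hold. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and adjustment over 32 lists. Chromosomes with at least 50 tested genes were tested in the same way. An epithelial score, the mean log2 CPM of the epithelial junction list minus that of the mesenchymal list, was compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 libraries against 3.

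The named genes are 16 genes fixed in advance, the 12 with the highest fold change in each direction among genes past the threshold with a mean count of at least 20 and groups that do not overlap (predicted models, pseudogenes and receptor segments left out), and from each list up to 4 members with the smallest p-value. Some list members that the rule selects are not reported here. A gene outside this rule is named as chosen after its values were seen. The alternatives were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom with and without quality weights, other count filters, counts thinned to the smallest library, a replicate block, each library left out, a 2-fold minimum, camera on ranks, on voom values or with an estimated correlation, fry, and other prior counts. Added after the data had been seen were summed transcripts, the 5 complete libraries with all rows, a run without the genes of the other cell types' marker lists, and library totals for the lists.

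The gene test was checked on counts simulated for this comparison, with 13718 genes tested and 50 genes changed at each fold. It recovered 64% of the genes changed 1.2-fold, 82% at 1.5-fold, 96% at 2-fold and 98% at 4-fold, with 18 false calls. Camera recovered 3 of 3 shifted sets and called 0 of 27 unshifted sets. The simulation drew genes independently and changed few of them, whereas 80.7% of genes were called in the data. It therefore does not show how camera treats lists of correlated genes, for which estimated correlations reached 0.76. Pairs of libraries in a group differed by 2.25 to 4.95 times the median chi-square of counting noise. As the counting options are unknown, this does not show whether a pair could be 1 library sequenced again.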

Results

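Gene expression was measured in 3 EL and 3 PT sphere libraries to ask how spheres grown from mammary glands before a tumour can be felt differ from spheres grown from established tumours of the same transgenic line. Total counts over transcripts were 69759793, 72808910 and 73654058 for EL replicates 1 to 3, the first from a table that is incomplete, and 78054335, 81804624 and 85126630 for PT replicates 1 to 3. After filtering, 13844 genes were tested. Libraries of a group were close, with correlations of log2 CPM across genes of at least 0.995 within EL and 0.997 within PT, against 0.839 to 0.847 between the groups. The biological coefficient of variation was 0.039.

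Transcripts of fibroblast markers were far lower in PT than in EL spheres. Most genes of the epithelial junction list and of the luminal progenitor and alveolar list were higher. Col3a1, a fibrillar collagen, fell from 22448 ± 922 CPM in EL to 124 ± 17.7 in PT (mean ± SD, n = 3 each; log2 fold change -7.50, SE 0.10). Krt8, a keratin of luminal epithelium, rose from 456 ± 4.62 to 1834 ± 45.3 CPM (log2 fold change 2.01, SE 0.03). The edgeR quasi-likelihood test called 11173 of 13844 genes, 5527 higher and 5646 lower in PT. Large changes went mostly 1 way, since 2681 of the genes changed over 2-fold were lower in PT and 1305 higher, and 966 genes fell and 24 rose over 16-fold. The values of the 2 groups did not overlap for 82.7% of genes, where chance gives 10%. With library totals in place of TMM factors, all log2 fold changes shifted by a median of 0.25, 65.8% instead of 49.5% of the called genes were higher in PT, and 381 calls changed direction, so changes of that size are relative to the scaling. Against a 2-fold minimum, edgeR called 3401 genes, 1010 higher and 2391 lower.

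**Figure D1:**
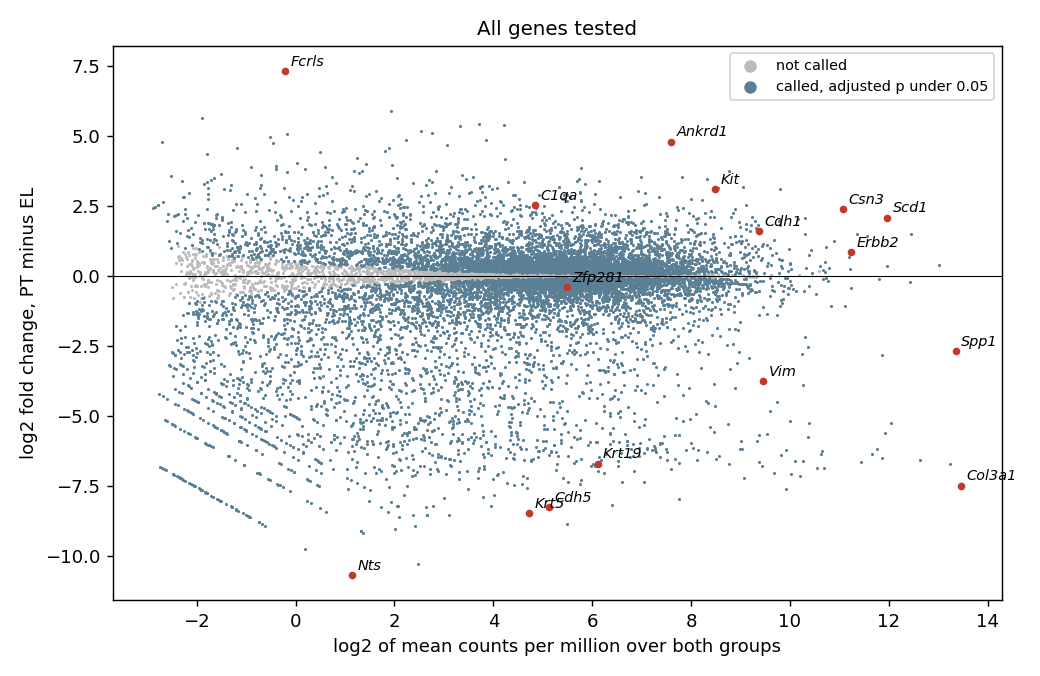
Each point is 1 of 13844 genes, with its log2 mean CPM over both groups on the x axis and its log2 fold change, PT minus EL, on the y axis; blue genes passed the edgeR test and red genes are named. More genes lie far below 0 than far above it (966 against 24 over 16-fold), and the parallel lines at the lower left are genes with few counts in PT.

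Among the genes fixed in advance, Cdh1, Epcam, Krt8 and Krt18 rose and Zeb1, Twist1, Snai2 and Vim fell in PT. Erbb2 (mouse chromosome 11, 98412484 to 98437716), the gene whose rat form is the transgene, was at 1730.5 ± 158 CPM in EL and 3085.5 ± 102 in PT (log2 fold change 0.83, SE 0.05; adjusted p = 1.20e-08 by edgeR). The adhesion genes Cdh1 (chromosome 8, 106603350 to 106670247) and Epcam rose by 1.60 (SE 0.04) and 1.28 (SE 0.03) on the log2 scale, and Krt18 by 2.05 (SE 0.03). The Erbb2 rise was smaller than these and than the median of the epithelial junction list (log2 fold change 1.49). It was not separated from a change in the share of epithelial cells. Zeb1 and Twist1, transcription factors that repress epithelial genes, fell from 43.8 ± 1.71 to 0.825 ± 0.172 CPM and from 40.1 ± 2.04 to 0.507 ± 0.115 CPM. Snai2 fell from 21.9 ± 1.65 to 0.708 ± 0.150. Vim, an intermediate filament protein of mesenchymal cells, fell from 1314.5 ± 48.4 to 95.9 ± 7.58 CPM (log2 fold change -3.78, SE 0.05).

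The basal keratins did not move together. Krt5 fell from 52.5 ± 5.67 to 0.143 ± 0.0270 CPM (log2 fold change -8.49, SE 0.15). Its usual partner Krt14 stood at 149 ± 5.90 in EL and 178 ± 6.88 in PT (log2 fold change 0.26, SE 0.04). Zfp281 (chromosome 1, 136624901 to 136630391), a zinc finger regulator of pluripotency and mesenchymal genes, was lower in PT, at 38.4 ± 1.64 against 51.2 ± 1.13 CPM (log2 fold change -0.42, SE 0.04; adjusted p = 8.54e-07 by edgeR). Nr2f1, a nuclear receptor linked to tumour cell dormancy, fell from 11.4 ± 1.22 to 0.315 ± 0.167 CPM. This fall stood beside those of the fibroblast and endothelial markers (medians -6.59 and -5.67), and which cells made the transcript was not tested. The cell cycle inhibitor Cdkn1b rose from 68.0 ± 2.79 to 133 ± 4.38 CPM. The proliferation marker Mki67 fell from 63.3 ± 3.17 to 26.6 ± 1.75 CPM (log2 fold change -1.25, SE 0.05). Ccnd1, cyclin D1, was the 1 gene of the 16 that did not pass (143 ± 2.40 and 146 ± 2.18 CPM; adjusted p = 0.331 by edgeR); it passed with library totals (log2 fold change 0.28) and with upper-quartile factors (0.09).

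**Figure D2:**
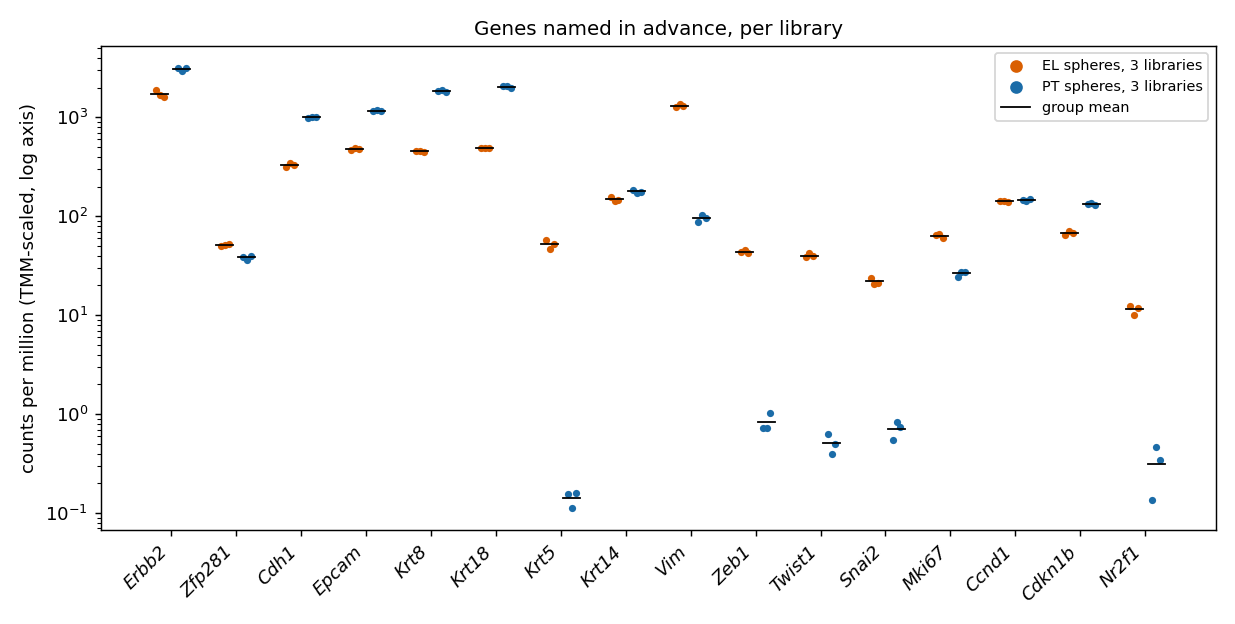
CPM (log axis) of the 16 genes fixed in advance, with 1 point per library (orange EL, blue PT, 3 each) and a bar at the group mean. Krt5, Zeb1, Twist1, Snai2 and Nr2f1 lie lowest in the PT libraries, and Ccnd1 lies at the same height in both groups.

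The 12 genes that fell most included several that are known from blood vessel endothelium. Cldn5, the endothelial claudin, had 1349 counts over the EL libraries and 1 over the PT libraries, a ratio of 1794 (95% interval 321 to 70907). Tmem100 gave a ratio of 823 (interval 147 to 32564), Gpihbp1, which holds lipoprotein lipase on capillaries, 799 (interval 143 to 31619), Ppp1r16b 798 (interval 143 to 31566), Eltd1 642 (interval 177 to 5306) and Folh1 566 (interval 193 to 2748.5). Nts, the neuropeptide neurotensin, had 530 counts in EL and 0 in PT and was at least 235-fold lower, and Reg3g, an antimicrobial lectin, was at least 122-fold lower. Gjb5, Olfml1 and Stmn2, also at 0 in PT, were at least 69.6-fold, 66.5-fold and 63.8-fold lower, and Fndc1 had a log2 fold change of -8.88 (SE 0.13). Of these 12 genes, all with 0 to 3 PT counts except Folh1 moved over 1.5-fold with the method or with 1 library left out: Eltd1 was at -9.05 and, without PT replicate 1, at -11.52, and Nts at -10.69 and, with limma-voom, at -8.85 on the log2 scale.

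The 12 genes that rose most were of mixed kinds and mostly of low abundance. Fcrls, an Fc receptor-like gene of macrophages and microglia, had 1 count in EL and 277 in PT, a ratio of 208 (95% interval 37.1 to 8257). Csn1s2a, a casein, rose from 0.879 ± 0.0549 to 36.4 ± 0.427 CPM (log2 fold change 5.37, SE 0.08), and Ankrd1, a target of the YAP pathway, from 13.7 ± 2.09 to 375 ± 6.52 CPM (log2 fold change 4.78, SE 0.07). Erbb4, a partner receptor of Erbb2, rose from 0.0418 ± 0.0525 to 1.35 ± 0.0482 CPM. The log2 fold changes of the other 8 were 5.88 for Slc25a34, 5.41 for the muscle actin Acta1, whose reads may be shared with other actins, 5.36 for the adrenergic receptor Adrb1, 5.16 for Sidt1, 5.09 for Rtn1, 5.05 for Angptl7 (SE 0.41), 4.84 for Car8 and 4.83 for Lect1. Angptl7 had 6 counts in EL and 278 in PT, a ratio of 34.8 (95% interval 15.8 to 95.8), and its log2 fold change was 5.97 without EL replicate 1. Erbb4 had 5 counts in EL, and its value was 4.93 (SE 0.43) with all libraries and 6.49 without EL replicate 2. Fcrls moved from 7.30 to 9.38 without EL replicate 3.

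Of the 32 lists with at least 3 tested members, 16 were called by camera, 12 lower and 4 higher in PT, and fry called 28. The fry p-value tests whether the members of a list move on balance 1 way, its mixed p-value whether they move in either direction, and neither compares them with other genes. None of the 16 held with an estimated correlation between genes, where camera's lowest adjusted p was 0.244, 5 lists had an unadjusted p under 0.05, and 16 had one with the preset correlation. The count of members called by edgeR, adjusted over the list alone, equalled the count over all genes in every list but 1. The lists drawn on textbook knowledge share genes in places, and without genes that any marker list also holds camera again called 16.

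The mesenchymal program was lower in PT in all 25 of its members, with a median log2 fold change of -4.83 (camera adjusted p = 4.12e-09; adjusted p = 0.279 with an estimated correlation). Tnc, a matrix protein of remodelling stroma, fell from 7607 ± 193 to 154 ± 4.89 CPM. Sparc fell from 7369 ± 122 to 80.7 ± 7.18. Mmp14, a membrane-bound collagenase, had a log2 fold change of -4.83 (SE 0.05) and Fbn1, a microfibril protein, of -6.63 (SE 0.07). Markers of other cell types moved with this list: all 18 fibroblast markers were lower in PT, with a median of -6.59 (camera adjusted p = 9.00e-09; adjusted p = 0.408 with an estimated correlation), and so were all 12 endothelial markers, with a median of -5.67 (camera adjusted p = 5.02e-05; adjusted p = 0.244 with an estimated correlation). The fibroblast markers held 7.50 ± 0.288% of the counts in EL and 0.103 ± 0.00805% in PT (n = 3 each).

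Among the fibroblast markers, Col1a1 fell from 19014 ± 487 to 178 ± 16.4 CPM and Pdgfra, the receptor used to mark fibroblasts, from 402 ± 25.1 to 7.76 ± 0.363. Postn and Col5a1 had log2 fold changes of -5.25 (SE 0.05) and -6.86 (SE 0.06). Among the endothelial markers, the vascular cadherin Cdh5 fell from 69.5 ± 1.06 to 0.223 ± 0.101 CPM and Pecam1 from 47.4 ± 2.16 to 0.266 ± 0.0978. Eng and Plvap had log2 fold changes of -4.06 and -5.19. All 7 pericyte markers were lower (median -3.53; camera adjusted p = 0.00261, and adjusted p = 0.279 with an estimated correlation), among them Cspg4, at -5.33 (SE 0.05), Abcc9, Mcam and Rgs5. The 4 tested adipocyte markers, Lpl, Fabp4, Pparg and Plin4, were lower as well (median -2.75; camera adjusted p = 0.0430, and adjusted p = 0.408 with an estimated correlation). The call was lost without EL replicate 1 (adjusted p = 0.0577) and on voom values. Plin4 itself (log2 fold change -0.73, SE 0.25) did not pass with library totals, with DESeq2, in the 5 complete libraries, or without EL replicate 1, EL replicate 2 or PT replicate 1.

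The epithelial junction program was higher in PT in 24 of 25 members, with a median log2 fold change of 1.49 (camera adjusted p = 2.10e-08; adjusted p = 0.244 with an estimated correlation). Cldn3, a tight junction protein, rose from 161 ± 5.56 to 756 ± 16.6 CPM. The exception was Krt19, a keratin of luminal cells, which fell from 137 ± 7.17 to 1.31 ± 0.400 CPM (log2 fold change -6.71, SE 0.10) while Krt8 and Krt18 rose 4.02-fold and 4.15-fold. The score of epithelial minus mesenchymal expression was -1.96 ± 0.07 in EL and 3.77 ± 0.12 in PT (SD, n = 3 each), a difference of 5.73 with no overlap (exact two-sided permutation p = 0.1, the smallest this design allows).

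Milk protein and luminal progenitor genes were higher in PT in 15 of 18 members and lower in 2, with a median of 1.06 (camera adjusted p = 0.000170; adjusted p = 0.244 with an estimated correlation). Kit, the receptor that marks luminal progenitors, rose from 75.7 ± 4.05 to 642 ± 11.5 CPM, the casein Csn3 from 690.5 ± 32.2 to 3595 ± 50.2, and Lcn2, a secreted iron-binding protein, from 2940.0 ± 114 to 8281 ± 154. The list's median lay below that of the epithelial junction list (1.49). The rise of the list as a whole was not separated from a higher share of epithelial cells. Hormone-sensing luminal genes went both ways, with 4 higher and 6 lower of 11 (camera adjusted p = 0.418). Gata3, the luminal transcription factor, rose by 1.85 (SE 0.05), whereas the values were -5.93 (SE 0.11) for Tbx3, -3.28 for Ly6a and -8.54 (SE 0.24) for Tnfsf11, the RANK ligand. The basal and myoepithelial list was also split, with 8 members higher and 11 lower of 20 (camera adjusted p = 0.467). The oxytocin receptor gene Oxtr and Krt17 rose by 3.52 and 2.79 on the log2 scale, and Cxcl14 and Tagln were at -4.07 and -2.79.

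**Figure D3:**
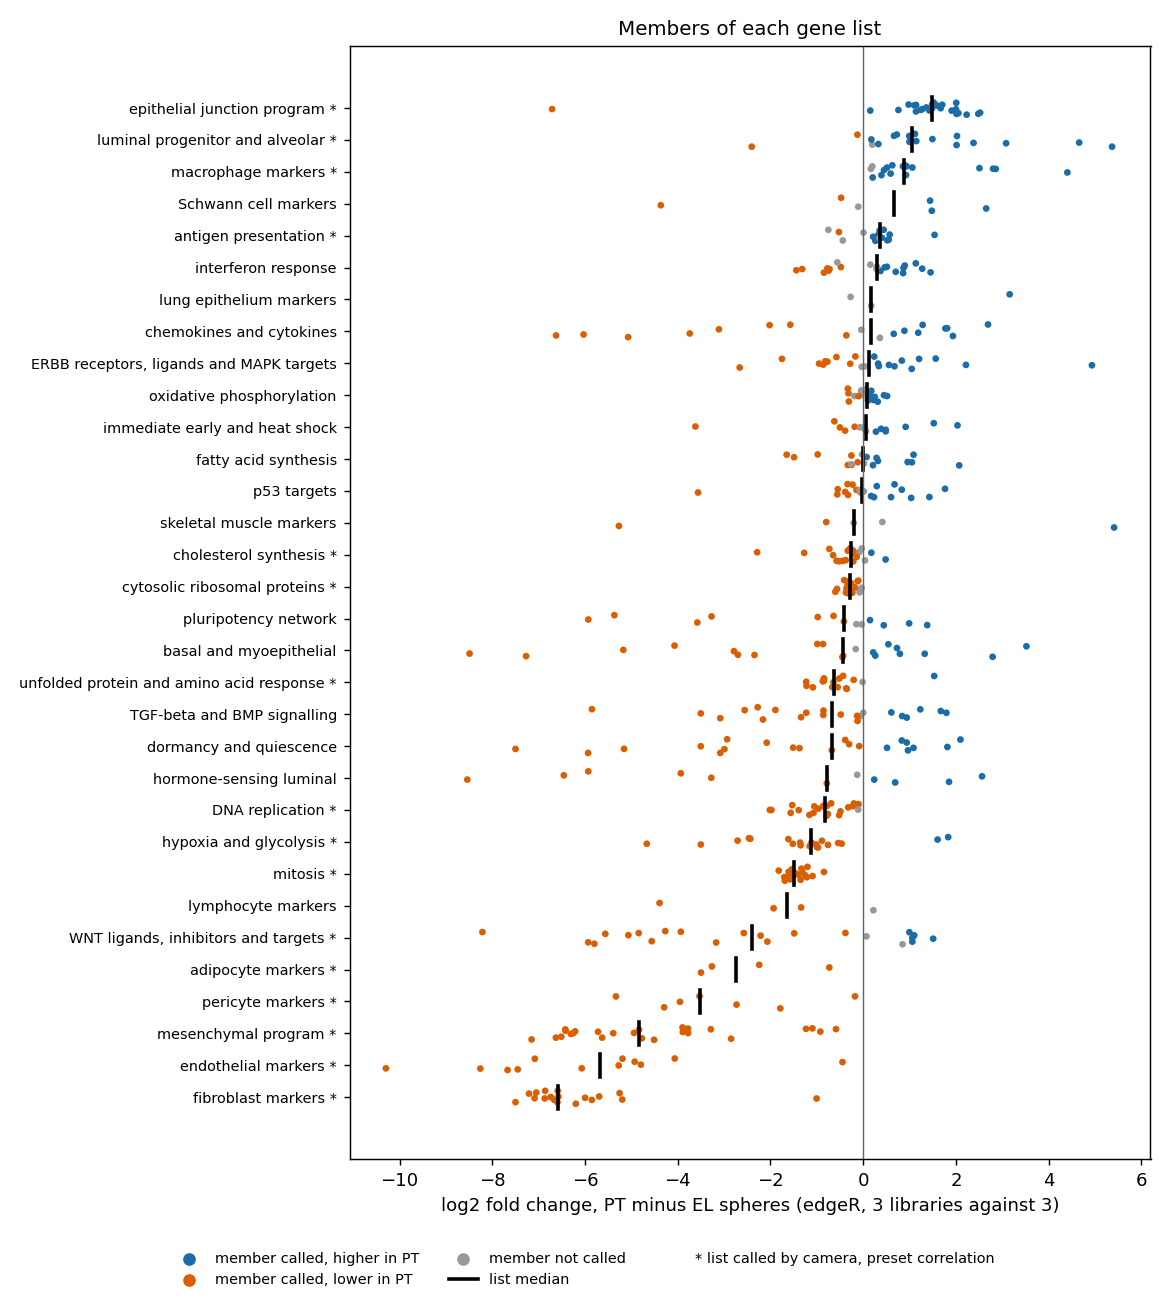
Log2 fold changes, PT minus EL, of the tested members of 32 gene lists, with 1 point per gene (blue called higher in PT, orange called lower, grey not called), a black bar at each list's median, and an asterisk on the 16 lists called by camera with a preset correlation. Fibroblast, endothelial and mesenchymal members lie far to the left (medians -6.59, -5.67 and -4.83) and epithelial junction members to the right (median 1.49), with Krt19 alone at -6.71.

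Cell cycle genes were lower in PT. All 20 mitosis genes fell, with a median of -1.48 (camera adjusted p = 6.60e-06; adjusted p = 0.494 with an estimated correlation), among them Top2a, from 88.0 ± 6.15 to 27.3 ± 1.27 CPM, Cdk1 (log2 fold change -1.58) and Tpx2 (-1.47). Of 22 DNA replication genes 21 fell, with a median of -0.82 (camera adjusted p = 5.02e-05; adjusted p = 0.575 with an estimated correlation), among them E2f1 (-1.56), Rrm2 (-2.01), Ccne1 (-1.98) and Mcm6 (-0.97), while with library totals 17 were lower and 2 higher. In the list of dormancy and quiescence genes 7 were higher and 14 lower of 21 (camera adjusted p = 0.188). The collagen receptor gene Ddr2 and Gas1 had log2 fold changes of -5.93 (SE 0.07) and -2.99 (SE 0.04), and Gas6, a ligand of TAM receptors, rose by 2.10 (SE 0.04) on the log2 scale. The fall of the mitosis and replication lists, and of most genes of the dormancy list, went with the fall of the fibroblast and endothelial markers given above.

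Genes of hypoxia and glycolysis were lower in PT in 18 of 20 members, with a median of -1.13 (camera adjusted p = 4.00e-04; adjusted p = 0.592 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase, fell from 684 ± 101 to 26.9 ± 1.18 CPM. Hk2, Pfkfb4 and the glucose transporter gene Slc2a1 had log2 fold changes of -2.46, -3.50 and -1.35. The list fell beside the fibroblast and endothelial markers (medians -6.59 and -5.67). The 2 members that rose, named here after their values were seen, were Car9 (1.61) and Egln3 (1.83). Genes of the unfolded protein and amino acid response were lower in 16 of 18 members and higher in 1, or 15 and 2 with library totals, and fell beside the same fibroblast and endothelial markers (median -0.62; camera adjusted p = 9.27e-04, and adjusted p = 0.244 with an estimated correlation), among them the chaperones Hspa5 (-0.85), Hsp90b1 (-0.87) and Calr (-0.67), and Trib3 (-1.23).

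Cholesterol synthesis genes were lower in 15 of 20 members and higher in 2, with a median of -0.26 (camera adjusted p = 0.0434; adjusted p = 0.712 with an estimated correlation), among them Cyp51 (-2.29) and Hmgcs1 (-0.38). That call ended on ranks (0.0902), with library totals (0.168, with 8 members lower and 5 higher), and without EL replicate 1 (0.0590), EL replicate 3 (0.0594), PT replicate 2 (0.0842) or PT replicate 3 (0.0563). Cytosolic ribosomal protein genes were lower in 17 of 20 (median -0.28; camera adjusted p = 0.00153, and adjusted p = 0.551 with an estimated correlation), among them Rplp0, Rplp1 and Rpl18. With library totals 9 were lower and 5 higher and the call ended (0.169). The cholesterol and ribosomal lists also fell beside the fibroblast and endothelial markers (medians -6.59 and -5.67). Fatty acid synthesis genes were split, with 8 higher and 7 lower of 18 (camera adjusted p = 0.795; median -0.00, mean 0.04, and with library totals 11 higher and 4 lower). Scd1, the stearoyl-CoA desaturase gene, rose from 1535 ± 98.4 to 6451 ± 175 CPM and Srebf1 by 1.09, and Fads1 and Acsl3 were at -1.65 and -0.98. Of the oxidative phosphorylation genes 10 were higher and 4 lower of 20 (camera adjusted p = 0.404), and with library totals 16 were higher and 1 lower, with Ndufa4 (0.45), Uqcrfs1 (0.52) and Atp5o (-0.33) as examples.

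Macrophage markers were higher in PT in 16 of 18 members, and in 17 when adjusted over the list alone, with a median of 0.87 (camera adjusted p = 0.00148; adjusted p = 0.592 with an estimated correlation). The complement genes C1qa, C1qb and C1qc rose from 8.62 ± 1.27 to 49.0 ± 4.26, from 2.40 ± 0.587 to 17.4 ± 1.52 and from 3.59 ± 0.396 to 25.0 ± 2.03 CPM. The chemokine receptor gene Cx3cr1 rose from 0.124 ± 0.0864 to 2.69 ± 0.254 CPM (log2 fold change 4.40, and 5.12 without EL replicate 3). Antigen presentation genes were higher in 10 of 15 members and lower in 1 (median 0.35; camera adjusted p = 0.0434, and adjusted p = 0.592 with an estimated correlation), among them H2-K1 (0.57), Tapbp (0.44), Psmb8 (0.35) and H2-DMb1 (1.54). This call ended on ranks (0.0558), with library totals (0.109) and without EL replicate 1 (0.0950). H2-Ab1, a class II chain whose row is missing from EL replicate 1, was lower in PT in the 5 complete libraries, at 1.48 ± 0.329 against 8.69 ± 0.361 CPM (n = 3 and 2; log2 fold change -2.55, SE 0.14). Of the 4 tested lymphocyte markers, Il2rb (-4.39), Lck (-1.93) and Cd4 (-1.34) were lower in PT and Ltb did not pass (camera adjusted p = 0.311). Il2rb had 7 counts in PT, and its value was -5.50 without PT replicate 2 and -3.80 without PT replicate 3.

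By camera with the preset correlation, WNT was the 1 signalling list called, while fry also called TGF-beta and BMP signalling (adjusted p = 1.91e-05). WNT ligands, inhibitors and targets were lower in 15 of 22 members and higher in 5, with a median of -2.39 (camera adjusted p = 0.0434; adjusted p = 0.289 with an estimated correlation). With library totals 15 were lower and 7 higher. Lgr5, the stem cell receptor of R-spondins, fell from 13.7 ± 1.32 to 0.0434 ± 0.0285 CPM (log2 fold change -8.21, and -8.80 without PT replicate 2). Dkk3, Wnt11 and Wnt5a had log2 fold changes of -5.93, -5.56 and -2.58. The list fell beside the fibroblast and endothelial markers, of which 18 of 18 and 12 of 12 were lower (medians -6.59 and -5.67). The WNT call ended without EL replicate 1 (0.0638) and on voom values (0.0785). In the list of ERBB receptors, ligands and MAPK targets 11 were higher and 9 lower of 22 (camera adjusted p = 0.634; with library totals 13 and 7). Erbb3 and Grb7 rose by 1.56 (SE 0.06) and 1.21 (SE 0.05) on the log2 scale, and Hbegf and Fosl1 were at -0.95 (SE 0.04) and -1.75 (SE 0.06). TGF-beta and BMP genes were higher in 6 and lower in 14 of 22 (camera adjusted p = 0.180; with library totals 10 and 12). Fst, Tgfbr2 and Tgfb1 were at -5.85, -1.89 and -2.28, and Ltbp2 rose by 1.79. The pluripotency network had 4 higher and 7 lower of 13 (camera adjusted p = 0.397), with Klf2 (-3.27), Klf4 (-0.98) and Klf5 (1.38) as examples beside Zfp281.

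The remaining lists held changes in both directions. Among chemokines and cytokines 8 were higher and 8 lower of 18 (camera adjusted p = 0.982; the median was 0.16, the mean -0.89 and camera's direction lower). Ccl8, a monocyte attractant, fell from 119 ± 10.1 to 1.82 ± 0.133 CPM and Il33 had a log2 fold change of -6.62, while Lif and Cxcl16 rose by 1.81 and 1.94. Interferon response genes were higher in 10 and lower in 7 of 21 (camera adjusted p = 0.467), with Ddx58 (1.14), Ifih1 (0.90) and Oas1a (1.27), and Bst2 was at 45.4 ± 4.42 CPM in PT and 37.6 ± 4.96 in EL in the 5 complete libraries. Of the p53 targets 9 were higher and 8 lower of 20 (camera adjusted p = 0.634; median -0.02, mean 0.04, and with library totals 13 higher and 4 lower), with Perp (1.77), Fas (1.43), Epha2 (1.04) and Pmaip1 (-3.56). Immediate early and heat shock genes were higher in 7 and lower in 5 of 16 (camera adjusted p = 0.462; with library totals 11 and 3), with Hspb1 (2.03), Ier3 (1.52), Zfp36 (0.92) and Egr2 (-3.62).

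Markers of 3 further cell types were tested and not called by camera. Schwann cell markers were higher in 3 and lower in 2 of 6 (camera adjusted p = 0.600), with Sox10 (1.48), Mbp (1.44), S100b (2.65) and Ncam1 (-4.36). Of 5 skeletal muscle markers, Acta1 rose, Tnni2 (-0.80) and Tnnt3 fell, Tnnt3 with 99 counts in EL and 3 in PT (ratio 43.9, 95% interval 14.6 to 216; log2 fold change -5.27, and -6.11 without PT replicate 1), and 2 members, among them Atp2a1 (0.41), did not pass (camera adjusted p = 0.948; the median was -0.20, and 0.04 with library totals). Of 3 tested lung epithelium markers, Sftpd rose from 8.07 ± 0.849 to 72.1 ± 3.27 CPM, and Ager (0.17) and Napsa (-0.27) did not pass (camera adjusted p = 0.467), although Ager passed with library totals (0.42). The erythroid list had 1 tested member, Alas2 (0.10, not called), and the 13 mitochondrial genome genes have no rows, so neither list was tested.

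No chromosome moved as a whole. Of 20 chromosomes tested with camera, 0 were called (lowest adjusted p = 0.967), 0 had an unadjusted p under 0.05, and 0 were called with an estimated correlation. Chromosome medians lay between -0.10 and 0.08 on the log2 scale. Of the 1445 tested genes whose rows are missing from EL replicate 1, edgeR called 492 higher and 432 lower in PT in the 5 complete libraries.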

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

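The runs with summed transcripts, with the 5 complete libraries, without the marker genes, and with library totals for the lists were chosen after the data had been seen. Genes called were 11158 with summed transcripts, 12197 in the 5 complete libraries and 11102 without the marker genes, against 11173, and 11008, 10887 and 11083 of the called genes kept their call and direction. Leaving out each library in turn gave 10758 to 11283 called genes, 5277 to 5575 higher and 5481 to 5708 lower. DESeq2 called 11047 genes and limma-voom 11158. A 2-fold minimum left 3401 genes, 1010 higher and 2391 lower, by its construction. Of 3038 values of the 162 genes that the naming rule selects, 3028 kept direction and side of the threshold under the alternatives. The other values comprised 3 that newly passed, 2 of Ccnd1 and 1 of Ager, and 7 that no longer passed, 6 of them of Plin4. Lists called were 0 with an estimated correlation (5 at an unadjusted p under 0.05; 16 by camera with the preset one) and 28 with fry, which tests each list by itself, and 12 to 16 without 1 library. The skeletal muscle markers turned direction with fry (adjusted p = 0.000144), and the cause was not tested. The epithelial score difference stayed between 5.67 and 5.79 without 1 library.

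No sign of pairing by replicate number was seen, which does not exclude it. Correlations of deviations between same-numbered EL and PT libraries were 0.0222, 0.00839 and -0.00216. EL replicate 3 correlated best with PT replicate 2 (0.0265). With the replicate block, 11203 genes were called, 5539 higher and 5664 lower, 16 lists and 0 chromosomes, and the score difference was 5.73 (exact p = 0.25, the smallest 3 pairs allow). Depth limits low genes: a gene with 0 counts over a group has only a bound.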

Other observations

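Whole gene families, chosen after their values were seen, were counted as well, and the collagen and metalloproteinase families share members with the fixed lists. Of 28 tested Hox genes, the body-axis transcription factors, 26 were lower in PT by edgeR and 0 higher under each of 4 scalings, and 3 of them had 0 counts in all PT libraries. Hoxc10 and Hoxc8 had log2 fold changes of -8.23 (SE 0.13) and -5.62 (SE 0.10). Of 38 collagen genes 26 were lower and 10 higher, the latter including Col11a1 (log2 fold change 1.53) and Col4a5 (0.88). Of 20 matrix metalloproteinase genes 16 were lower and 2 higher (with library totals 14 and 3), with Mmp3 at -7.60 and Mmp15 at 2.23. These falls stood beside those of the fibroblast and endothelial markers (medians -6.59 and -5.67). The matrix protein gene Spp1 was among the most abundant transcripts, at 18166 CPM in EL and 2820.5 in PT.

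Further genes called higher by edgeR are given as single values, again chosen after those were seen. Cp, the copper carrier ceruloplasmin, was at 1646 CPM in EL and 4395 in PT, Wfdc18 at 187 and 1589, Slc5a8 at 60.4 and 813, and Ctgf, like Ankrd1 a YAP target, at 292 and 878. Among genes missing from EL replicate 1, the imprinted long RNAs H19, Meg3 and Rian had log2 fold changes of -7.04 (SE 0.09), -6.75 (SE 0.15) and -7.19 (SE 0.13) and Neat1 rose by 1.93 (SE 0.03), with n = 2 EL and 3 PT.

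All tests of explanations below were chosen after the results they bear on had been seen. The mesenchymal list was lower in PT in 25 of 25 members. A tissue label of the EL samples names lung. The lung epithelial transcripts Sftpa1, Sftpb, Sftpc and Scgb1a1 together had 10 counts in EL and 33 in PT. That argues against lung epithelial cells making these transcripts in the EL spheres. These genes do not mark lung fibroblasts or vessel cells, so a lung origin of such cells stays open. The endothelial markers, none of which is on the mesenchymal list, fell with a median of -5.67, and Cdh5 fell from 69.5 to 0.223 CPM. These markers held only 0.0279% of the EL counts, against 7.50% for the fibroblast markers and 3.20% for the mesenchymal list. Fibroblasts, with some vessel cells, carried along in the EL spheres may account for the fall of the mesenchymal list. A mesenchymal state of the epithelial cells cannot be told apart from this, because bulk counts do not say which cell made a transcript and both predict 25 lower members. The age and stage of the mice, which differ with the group, stay open as well.

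The epithelial junction list rose in PT with a median of 1.49. The lowest median over 4 scalings was 1.48, and library totals shifted all log2 fold changes by a median of only 0.25. The choice among these 4 scalings thus does not account for the rise. An error shared by all 4 was not tested. Dilution of unchanged epithelial cells by other cells in EL would shift all members alike only if those cells made none of them. In the test, 18 of 25 lay over 3 standard errors from the median, from -6.71 to 2.52 with a median SE of 0.04. The SE measures a spread between libraries that may be technical, so this count cannot decide on dilution. How much of the rise comes from dilution stays open. What sets Krt19 apart from Krt8 and Krt18 was not tested.

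Macrophage markers rose in PT while fibroblast markers fell, and the medians lay 7.47 apart. A lower share of epithelial cells in PT that raised every other cell type alike would require both to rise, and they did not. Both medians were known before this comparison was set, so it adds no separate test. Dilution of the same macrophages by other cells in EL would shift all members alike only if those cells made none of them. In the test, 10 of 18 lay over 3 standard errors from the list's median of 0.87, from 0.17 to 4.40. The limit of 5 in 10 was set after the values were seen, and the SE may reflect technical spread. This count therefore cannot decide, and the rise may come from dilution or from more macrophages. A comparison of C1qa, C1qb and C1qc with the other members was set aside, because these genes had been picked as the top of the list. A changed state of the macrophages stays open and was not tested.

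With 6 libraries in 2 groups of 3 there are 10 splits, too few for a share under 0.05. The real split called 11173 genes by edgeR, and 0 was the highest count among the other splits, with at most 16 genes at an unadjusted p under 0.05, so 1 of 10 splits gave as many. For gene lists, 2 of 10 splits gave as many as the real one, 16, with camera and a preset correlation. The other splits called 10 to 16 lists, so this count does not set the real grouping apart. Those splits mix libraries of both groups, so they keep part of the group difference and also put it into the spread within each side. For genes, that spread leaves few calls in any mixed split. The count of 0 genes was therefore fixed by the design and does not measure chance. For chromosomes all 10 splits gave 0.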
